A study of Mus musculus with 75 samples.

How the data were processed

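The series describes RNA-seq, H3K27ac ChIP-seq and ATAC-seq of sorted hypothalamic nuclei from mice carrying a leptin receptor Cre driver and the SUN1-sfGFP tag. Of its 75 samples, 16 H3K27ac and 16 ATAC libraries were analysed here. The 23 RNA samples, 16 ChIP input samples and 4 ATAC input samples were not analysed here. Per the labels' protocols, hypothalami were pooled and nuclei sorted by flow cytometry as GFP-positive or GFP-negative, with 300000 to 540000 nuclei for ChIP-seq. Each library was placed in its group of treatment and sort from its title and the labelled treatment and sort. The labels used here give no sex for a library.

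Per the file headers, the authors deposited, for each assay, a table of normalized signal for every region and library, headed normalized counts. The method of that normalization is not given in the sources used here. Signal values carried 1 decimal, and within a library the low values fell on a ladder of unequal steps, so whole read counts could not be recovered and no count model was used. The number of distinct values below 20, a rough guide to how finely a library was sampled, was 11 to 62 per H3K27ac library and 8 to 39 per ATAC library. The same tables hold the authors' log2 fold changes and p-values with FDR for their own comparisons, per the file headers, and these are quoted only as the authors' values. The authors also deposited variance-stabilized values, which were not used. H3K27ac regions are pieces of larger domains by their names, and 65622 of 126368 directly adjoined the next region. The mean column of each table matched the mean of the 16 libraries to within rounding. The submitters' processing notes name build mm9 and the tools CASAVA 1.8, STAR 2.5.2b, Bowtie 1.2, Bowtie2 2.2.6, MACS2, HTSeq 0.6.0 and DESeq2 1.16.1, without saying which step each served. No peak caller or aligner is tied to either assay in the sources used here.

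Regions whose mean signal lay in the lowest 10% were left out (below 5.96 for H3K27ac and 5.44 for ATAC), which left 113725 and 43767 regions. Values were taken to log2(signal + 1) and fitted with limma 3.58.1 in R 4.3.3, with a mean for each of the 8 groups and an intensity-dependent prior on the variance. All groups shared the estimate of the spread, with 8 residual degrees of freedom before moderation. Fold changes are on the log2(signal + 1) scale, which understates changes of low regions. P-values are two-sided and were adjusted by Benjamini-Hochberg within each comparison over the regions tested, and a region was called at an adjusted p under 0.05. The comparisons were GFP-positive against GFP-negative over all treatments, Fast against Fed, Lep2 against Fast and Lep24 against Fast within each sort, and the difference of each of those changes between sorts. Overlaps used GenomicRanges 1.54.1, plots matplotlib 3.10.9 and data handling the R package data.table (version 1.17.8). Overlap between assays needed 1 bp. Coordinates are mm9 and count from 1, for which each deposited start was raised by 1.

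The design, the test, the rule for named regions and most alternatives were fixed before the data were examined. The rule named, for each comparison, the 8 higher and 8 lower called regions with the smallest p that changed the same way in both replicates, without overlap between the groups. For GFP-positive against GFP-negative it asked instead for the same sign in every pair of libraries with the same treatment and replicate number. The rule also covered a panel of genes and sets of genes. These parts were not run, since the files pair regions with no gene names and the reference tables at hand are of another build than mm9. Regions are therefore given by position only, with no gene, exon or intron. The alternatives were quantile normalization, no filter, pseudocounts of 0.1 and 5, the replicate number or the pair of libraries as a block, only the groups compared in the fit, an adjusted p of 0.01, and each library left out in turn. Alternatives chosen after seeing the data were library weights, the set of 6 H3K27ac libraries with summed mitochondrial signal above 5000 as a term, only the other 10 H3K27ac libraries, ATAC without 2 GFP-positive libraries that stood apart on principal components, and each Fast library in only 1 of the changes whose covariance was taken.

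The fits were tested on simulated data with the real regions' means and spreads and 200 changed regions. For GFP-positive against GFP-negative, log2 changes of 0.5, 1, 2 and 3 were recovered at 2%, 46%, 100% and 100% of changed H3K27ac regions and at 16%, 76%, 96% and 100% of changed ATAC regions. For Lep24 against Fast in GFP-positive nuclei, with 2 libraries per group, the shares were 0%, 2%, 46% and 82% for H3K27ac and 4%, 18%, 58% and 96% for ATAC. With a log2 change of 1 at 5686 H3K27ac regions the shares were 82.5% for the sort and 0.211% for Lep24 against Fast, and at 2188 ATAC regions 86.6% and 27.5%. The simulated noise was independent between regions and libraries, so the shares leave out structure among the libraries. The covariance between changes that share the Fast libraries was set beside 100 simulations of unchanged groups, with the spread estimated from the libraries kept for each pseudocount, normalization and smaller layout, and from all 16 where a lone Fast library was left out.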

Results

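H3K27ac, a histone mark of active promoters and enhancers, was measured by ChIP-seq and open chromatin by ATAC-seq in nuclei from the mouse hypothalamus. The mice carried a Cre driver at the leptin receptor gene and a Cre-dependent SUN1-sfGFP tag on the nuclear envelope, so that nuclei of cells with the long leptin receptor (LepRb) could be sorted as GFP-positive and the remaining hypothalamic nuclei as GFP-negative. Leptin is a hormone of fat tissue that falls in fasting and lowers food intake. There were 4 treatments: free feeding (Fed), a 36 h fast with saline (Fast), the same fast with leptin at 5 mg/kg given once at 34 h (Lep2, labelled 2 hours) and the fast with leptin given at 12, 24 and 34 h (Lep24, labelled 24 hours). With 2 sorts this made 8 groups of 2 libraries in each assay, 16 H3K27ac libraries and 16 ATAC libraries. The labels name pooled hypothalami and do not state whether the replicates came from separate pools of animals, so p-values measure only the spread between these samples, which may be technical.

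The H3K27ac table held 126368 regions with a median length of 1924 bp, and the table for ATAC held 48634 regions with a median length of 796 bp. The values were normalized signal, so read depth was unknown. Between replicates of a group, Pearson's r of log2 signal across regions ran from 0.88 to 0.966 for H3K27ac and from 0.798 to 0.911 for ATAC. No library was a copy of another (0 pairs with identical values). In ATAC, Fast GFP-positive replicate 2 had the largest share of regions at 0 (7.31%) and the fewest distinct values below 20 (8).

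In H3K27ac, 6 libraries stood apart from the other 10: replicate 1 of Fed, Lep2 and Lep24, in both sorts. Mitochondrial regions held 0.075 to 0.238% of their signal, against 0.0102 to 0.0384% in the other 10. Signal-dense autosomal regions exceeded sparse ones by 2.14 to 2.78 log2 units in the 6 libraries and by 3.50 to 3.82 in the other 10. The X chromosome held 0.70 to 0.86% of the signal in the 6 libraries and 1.11 to 1.42% in the other 10. Neither Fast replicate belonged to the 6, so every H3K27ac contrast with Fast was partly a contrast with this set of libraries.

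**Figure D1:**
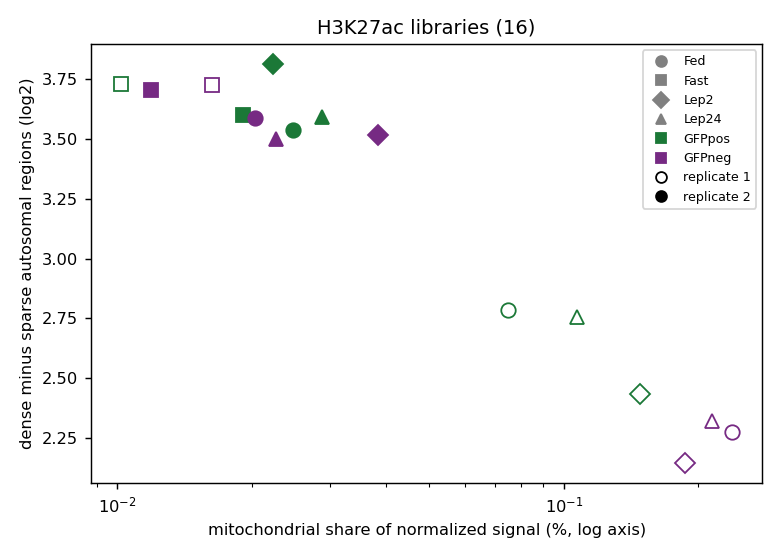
Each point is an H3K27ac library (16), with the mitochondrial share of normalized signal in percent on a log axis and the log2 difference between signal-dense and sparse autosomal regions on the vertical axis; shape gives the treatment, colour the sort and fill the replicate. The 6 open symbols at a mitochondrial share of 0.075% or more lie below 2.8 on the vertical axis, and the other 10 libraries lie at 3.5 or above.

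GFP-positive nuclei were compared with GFP-negative nuclei to find the chromatin that sets LepRb cells apart from the rest of the hypothalamus. H3K27ac differed at 10491 of the 113725 regions tested (9.22%), with 3707 regions higher and 6784 lower in GFP-positive nuclei. A 24997 bp region on chromosome 13 (117081229 to 117106225) carried 1340 ± 152 in GFP-positive and 678 ± 57.3 in GFP-negative libraries (mean ± SD of normalized signal, n = 8 libraries per sort). Among the lower regions, one on chromosome 9 (69608766 to 69619485) carried 92.5 ± 17.9 against 296 ± 57.6. Losses were larger than gains: 29.1% of the lower regions and 4.61% of the higher ones differed at least 2-fold.

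The 8 named regions with higher H3K27ac had log2 fold changes of 0.82 to 1.37. The region on chromosome 13 above gained 1.97-fold (log2 0.98, SE 0.10, limma adjusted p = 0.000802). A region on chromosome 12 (58636544 to 58643354) had the largest fold of the 8, at 2.59-fold, with 200 ± 41.2 against 77.2 ± 18.9. On chromosome 3, the regions 118896242 to 118902111 and 101582794 to 101587028 gained 2.23-fold and 2.09-fold. A short region on chromosome 13 (93163907 to 93165677) gained 2.30-fold, and regions on chromosome 4 (151995307 to 152003919) and chromosome 6 (99946167 to 99950955, and 5349686 to 5366051) gained 1.87-fold, 1.85-fold and 1.76-fold. The 8 named regions with lower H3K27ac had log2 fold changes of −1.86 to −1.55. The region on chromosome 9 above was 3.17-fold lower (log2 −1.66, SE 0.13, adjusted p = 0.000802). A region on chromosome 10 (40232387 to 40235418) fell 3.64-fold, from 104 ± 28.6 to 27.3 ± 5.12. The regions 15983802 to 15986381 and 31366236 to 31368725 on chromosome 16 fell 3.51-fold and 3.08-fold. Regions on chromosome 4 (117518040 to 117524372), chromosome 10 (56681278 to 56683978), chromosome 1 (139662105 to 139666042) and chromosome 2 (45211598 to 45214190) fell 3.36-fold, 3.33-fold, 3.25-fold and 2.93-fold. Regions were named only if their sign was the same in all 8 pairs of libraries with the same treatment and replicate number, which 2409 of the 3707 higher and 4696 of the 6784 lower regions met.

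The H3K27ac calls came from limma on log2(signal + 1), with Benjamini-Hochberg adjustment over 113725 regions, and 27662 regions had an unadjusted p under 0.05. In fits with treatment and sort as terms, the 6 libraries that stood apart called 4663 regions (2345 higher, 2318 lower) and the other 10 called 36822 (18666 higher, 18156 lower). Of the 10491 regions, 2058 were also called among the 6 libraries and 10254 among the 10, none with the opposite sign (0 in either set). The surplus of lower over higher calls was thus seen with all 16 libraries and not within either set. The count fell to 5188 without Lep24 GFP-positive replicate 2, 5267 without Fed GFP-positive replicate 2, 5540 and 5976 without Fast GFP-positive replicate 1 and 2, and 5856 and 6178 without Fast GFP-negative replicate 1 and 2.

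ATAC signal separated the same nuclei at 4287 of 43767 regions tested (9.80%), with 2041 regions more open and 2246 less open in GFP-positive nuclei. A region on chromosome 2 (157521665 to 157522613) carried 43.4 ± 9.26 in GFP-positive and 15.2 ± 2.23 in GFP-negative libraries (mean ± SD, n = 8 per sort). A region on chromosome 18 (68356514 to 68357065) was close to closed in GFP-positive nuclei, at 5.50 ± 3.21 against 36.9 ± 12.7. As with H3K27ac, a larger share of the lower than of the higher regions differed at least 2-fold, 41.5% against 19.7%.

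The 8 named regions that were more open had log2 fold changes of 1.19 to 1.92. The region on chromosome 2 above gained 2.71-fold (log2 1.44, SE 0.15, limma adjusted p = 1.37e-05). Folds were larger at 109797766 to 109798554 on chromosome 4 (3.78-fold) and at 172159996 to 172160547 and 180163158 to 180164073 on chromosome 2 (3.75-fold and 3.09-fold). Regions on chromosome 10 (79537321 to 79538525), chromosome 7 (20401364 to 20402171), chromosome 6 (5324651 to 5325569) and chromosome 9 (14830594 to 14831451) gained 2.93-fold, 2.59-fold, 2.37-fold and 2.27-fold. The 8 named regions that were less open had log2 fold changes of −2.70 to −1.15. A region on chromosome 16 (24282193 to 24282764) had the largest, 6.48-fold, from 35.1 ± 9.67 to 5.94 ± 4.63. The region on chromosome 18 above fell 6.17-fold (log2 −2.63, SE 0.26, adjusted p = 1.37e-05), and a region on chromosome 3 (150339760 to 150340307) fell 4.97-fold. Regions on chromosome 9 (14193269 to 14194032), chromosome 1 (184405083 to 184405908) and chromosome 14 (114334257 to 114334861) fell 3.48-fold, 3.31-fold and 3.18-fold. Regions on chromosome 10 (21372181 to 21373552) and chromosome 2 (116800429 to 116802029) fell 2.30-fold and 2.21-fold. The same sign in all 8 pairs, required for naming, was met by 1145 of the 2041 higher and 1378 of the 2246 lower regions.

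At an unadjusted p under 0.05 there were 11034 ATAC regions. Replicate 1 alone (8 libraries, treatment and sort as terms) called 4860 regions and replicate 2 alone 1230. The count fell to 2457 without Fast GFP-negative replicate 2, 2573 without Fed GFP-negative replicate 2, 2581 without Lep2 GFP-negative replicate 2, and 2734 and 2743 without Lep24 GFP-negative replicate 1 and 2.

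**Figure D2:**
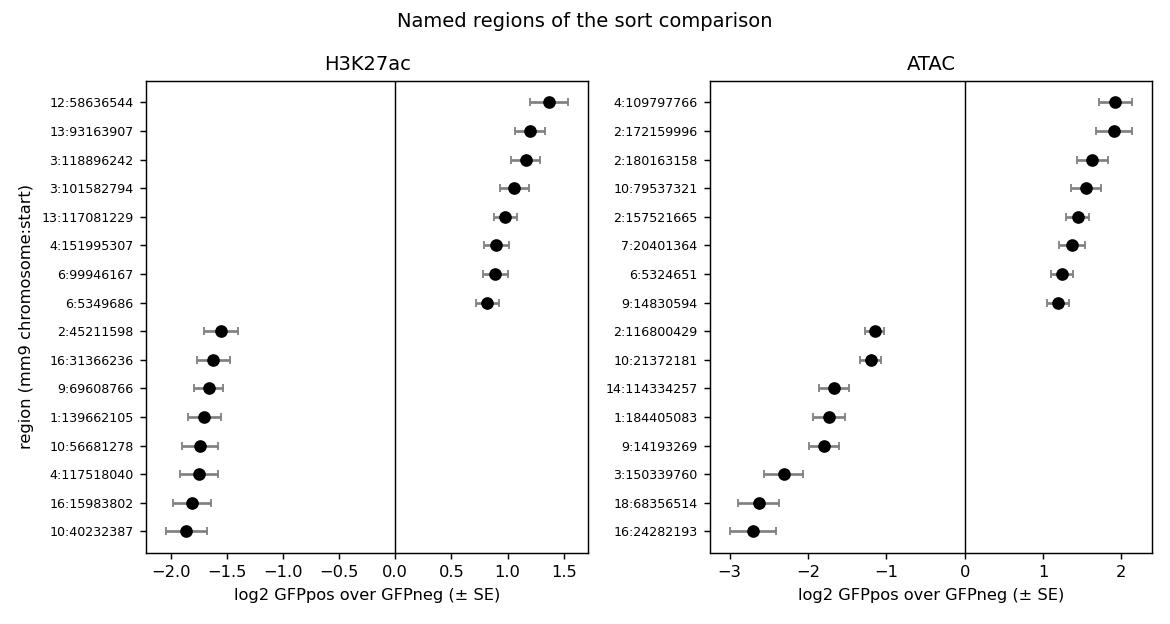
Log2 fold change of GFP-positive over GFP-negative nuclei (points, with bars of ± 1 SE from limma, on signal + 1) for the 8 higher and 8 lower named regions of H3K27ac and of ATAC, each labelled by its mm9 chromosome and start. Higher regions lie between 0.82 and 1.92, lower regions between −2.70 and −1.15.

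Open chromatin and H3K27ac were then compared at the same places, to see whether regions that were more or less open in LepRb nuclei also carried more or less of the mark. Of the 2041 ATAC regions that were more open, 427 (20.9%) overlapped an H3K27ac region called higher and 15 one called lower. Of the 2246 that were less open, 571 (25.4%) overlapped an H3K27ac region called lower and 10 one called higher. Independent lists would give 107.2 and 94.8 overlaps in the same direction, and 102.5 and 99.1 in the opposite direction. The ATAC region on chromosome 10 (21372181 to 21373552) lay over 2 H3K27ac regions, both called lower. The ATAC region on chromosome 6 (5324651 to 5325569) lay over an H3K27ac region that was higher by log2 0.77 (adjusted p = 0.00271). The H3K27ac region on chromosome 13 (117081229 to 117106225) held 3 ATAC regions, 2 of them called more open.

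Of the named regions, 6 of 8 H3K27ac gains and 3 of 8 H3K27ac losses overlapped a tested ATAC region. An ATAC call in the same direction was overlapped by 4 gains and 1 loss. All 8 ATAC gains and 6 of 8 ATAC losses overlapped a tested H3K27ac region. An H3K27ac call in the same direction was overlapped by 4 gains and 4 losses. No named region overlapped a call in the opposite direction (0 of 16 in either assay, those without any overlap included). Across 40383 overlapping pairs of regions Spearman's rho of the 2 sort contrasts was 0.32, and 0.69 over the 3633 pairs whose ATAC region was called. These correlations are across regions, which are not independent replicates. The share of ATAC calls matched in the same direction, 23.3%, was 51.8% with H3K27ac calls from the 10 libraries alone. That list of H3K27ac calls was longer, and a longer list overlaps more by length alone. With replicate 1 alone in both assays the share was 17.8%, and with replicate 2 alone 42.4%. Without Lep24 GFP-positive replicate 2 of H3K27ac the share was 14.9%, without Fed GFP-positive replicate 2 15.2% and without Fast GFP-positive replicate 1 15.5%.

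The sort difference in H3K27ac was not of equal size in all pairs of libraries. Over the 3633 pairs of regions with a called ATAC region, the H3K27ac difference between sorts rose by 0.51 to 0.63 per log2 unit of the ATAC contrast in 5 pairs of libraries. In the 3 pairs made of the 6 libraries that stood apart the slope was 0.13 to 0.22. ATAC pairs, set against the H3K27ac contrast at 4584 pairs of regions, had slopes of 0.30 to 0.73.

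**Figure D3:**
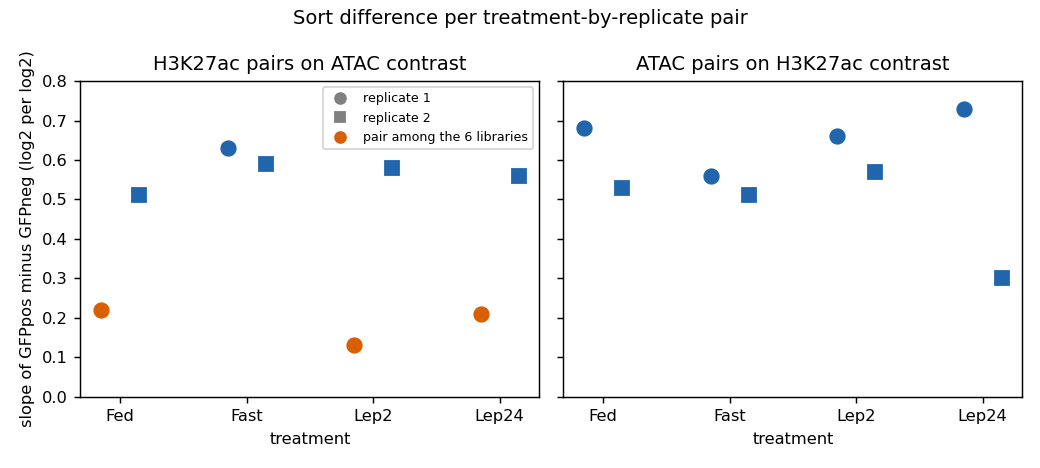
Each point is a GFP-positive minus GFP-negative pair of libraries, by treatment, and the vertical axis is the slope (log2 per log2) of its sort difference on the other assay's sort contrast, over overlapping regions called in that other assay. Orange points are the 3 pairs made of the 6 H3K27ac libraries with a high mitochondrial share, at 0.13 to 0.22, below the other 5 H3K27ac pairs at 0.51 to 0.63.

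The authors' deposited table lists 13389 H3K27ac regions at an FDR under 0.05 between sorts, of which 7729 were among the 10491 called here, all with the same sign (1235.1 expected for independent lists). The fold changes of that comparison in the authors' deposited table followed the sort difference over Fed and Fast (Spearman's rho across regions 0.985 for H3K27ac and 0.976 for ATAC) more closely than that over the 4 treatments (0.885 and 0.868). Those fold changes may thus weight the treatments unequally. Which libraries the authors' FDR rests on is not known. For ATAC the authors' deposited table lists 140 regions between sorts, and all 140 were among the 4287.

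Within single treatments the number of regions that differed between sorts depended on the settings and on single libraries. The authors' deposited table lists 7777 H3K27ac regions in Fast, 2374 in Lep24 and 1668 in Lep2, and 0, 0 and 8 ATAC regions in the same order. The limma fit, a comparison of 2 with 2 libraries added after the results were seen, called 117 H3K27ac regions in Fast (3 higher, 114 lower) and 0 in Lep24, Lep2 and Fed (8859, 7807 and 8687 at an unadjusted p under 0.05). The count in Fast was 11428 with the set of 6 libraries as a term, 16168 with library weights and 22642 in a fit without the 6 libraries. With the set as a term the counts were 3736 in Lep24, 2576 in Lep2 and 3308 in Fed, and without the 6 libraries, which left 1 with 1 library in these treatments, 12234, 10567 and 6141. The count in Fast was 11 and 0 without GFP-negative replicate 1 and 2 and 1 and 0 without GFP-positive replicate 1 and 2 (9218 and 8662 at an unadjusted p under 0.05 in limma where it was 0). In Lep24 it was 8 without GFP-negative replicate 1 and 1 without GFP-positive replicate 1, and in Fed 6 and 7 without GFP-negative replicate 1 and 2. In the H3K27ac fit without the 6 libraries, only the Fast groups kept 2 libraries, so Fast alone gave the spread. For ATAC the limma fit called 24 regions in Fast, 87 in Lep2, 7 in Fed and 0 in Lep24 (2720 at an unadjusted p under 0.05). Without GFP-negative replicate 1 and 2 and GFP-positive replicate 1 and 2 in turn, the ATAC counts were 48, 0, 1923 and 74 in Fast, 63, 0, 873 and 4 in Lep2, 20, 0, 116 and 5 in Fed, and 5, 1, 15 and 16 in Lep24. The ATAC counts of 0 without GFP-negative replicate 2 stood beside 2964, 2841 and 2396 regions at an unadjusted p under 0.05 in limma.

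Fast was compared with Fed to find chromatin that changes with 36 h without food. No region passed the threshold in either sort or assay (limma, 0 regions in each). The H3K27ac region with the smallest p in GFP-positive nuclei, on chromosome 5 (67996981 to 67997779), was listed at 0 in both Fast libraries and at 7.5 in both Fed libraries. In GFP-negative nuclei it was a region on chromosome 11 (60976465 to 60976889), at 5.8 and 12.7 in Fast and listed at 0 in both Fed libraries. The ATAC regions with the smallest p were on chromosome 1 (166161959 to 166162738) in GFP-positive nuclei, at 3.2 and 0 in Fast against 18.0 and 11.1 in Fed, and on chromosome 9 (72816033 to 72816741) in GFP-negative nuclei, at 17.7 and 31.2 against 8.8 and 8.5. These 4 regions, and those with the smallest p under leptin, were chosen after their values were seen.

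At an unadjusted p under 0.05, Fast against Fed gave 2176 H3K27ac regions in GFP-positive and 6801 in GFP-negative nuclei, and 2871 and 863 ATAC regions. The smallest adjusted p was 0.985 and 0.716 for H3K27ac, and 0.282 and 1 for ATAC. The test of whether the change differed between sorts also called 0 regions, with 2680 H3K27ac and 1728 ATAC regions at an unadjusted p under 0.05. The 95% confidence interval of a log2 change within a sort had a median reach of 0.86 to either side for H3K27ac and 0.82 for ATAC. In simulated data with groups of 2, a log2 change of 1 was recovered at 2% of H3K27ac and 18% of ATAC regions and a change of 2 at 46% and 58%, so most changes below about log2 2 were not detectable. Among the 10 H3K27ac libraries, with Fed left at 1 library per sort, 1 region was called in GFP-positive and 99 in GFP-negative nuclei, all 99 higher in Fast. Among the 10, only the Fast groups kept 2 libraries, so Fast alone gave the spread of that fit and its counts are a weak guide. Within the 6 libraries there was no Fast library and no such contrast. In ATAC, any fit without Fast GFP-positive replicate 1, here or under leptin, had replicate 2 as its only Fast control in these nuclei. That library had 7.31% of its regions at 0, the most of any ATAC library. Leaving out an H3K27ac library gave 1 call without Fast GFP-positive replicate 1, and in GFP-negative nuclei 8 without Fast replicate 1, 2 without Fed replicate 1 and 25 without Fed replicate 2. It gave 1 call in the test between sorts without Fast GFP-negative replicate 1. For ATAC, leaving out Fast GFP-positive replicate 1 gave 1382 calls and 594 between sorts. Leaving out Fast GFP-positive replicate 2 gave 4 and 1, Fed GFP-positive replicate 1 28, and Fast GFP-negative replicate 1 7 in GFP-negative nuclei.

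Lep2 was compared with Fast to find chromatin that responds to a single injection of leptin late in the fast. No region passed the threshold in either sort or assay (limma, 0 regions in each). The H3K27ac region with the smallest p in GFP-positive nuclei was the one on chromosome 5 (67996981 to 67997779) named for fasting, listed at 0 in both Fast libraries and at 12.6 and 4.0 in Lep2. In GFP-negative nuclei it was on chromosome 7 (71398167 to 71398868), at 11.5 and 8.0 in Lep2 and listed at 0 in both Fast libraries. The ATAC region with the smallest p in GFP-positive nuclei, on chromosome 9 (63638970 to 63639976), carried 28.3 and 25.7 in Lep2 against 8.7 and 0 in Fast. In GFP-negative nuclei it was on chromosome 15 (76008431 to 76008806), listed at 0 in both Lep2 libraries and at 4.7 and 6.7 in Fast.

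At an unadjusted p under 0.05, Lep2 against Fast gave 3721 H3K27ac regions in GFP-positive and 5265 in GFP-negative nuclei, and 3434 and 656 ATAC regions. The smallest adjusted p was 0.923 and 0.722 for H3K27ac, and 0.165 and 1 for ATAC. The test between sorts called 0 regions, with 2689 H3K27ac and 1744 ATAC regions at an unadjusted p under 0.05. The fit of the 10 H3K27ac libraries again took its spread from the Fast groups alone. Among the 10 H3K27ac libraries, with Lep2 left at 1 library per sort, the calls were 1 in GFP-positive and 0 in GFP-negative nuclei (9168 at an unadjusted p under 0.05, limma). Leaving out an H3K27ac library gave 1 call without Fast GFP-positive replicate 1 and 5 without Fast GFP-negative replicate 1. For ATAC, leaving out Fast GFP-positive replicate 1 gave 1492 calls and 503 between sorts, and leaving out Lep2 GFP-positive replicate 1 gave 415 and 43. Calls also appeared without Fast GFP-positive replicate 2 (4), Fast GFP-negative replicate 1 (7) and Lep2 GFP-negative replicate 1 (2).

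Lep24 was compared with Fast to find chromatin that responds to leptin repeated through the fast. No region passed the threshold in either sort or assay (limma, 0 regions in each). The nearest was an ATAC region on chromosome 6 (85806164 to 85806613) in GFP-positive nuclei, at 4.6 and 14.5 in Lep24 and listed at 0 in both Fast libraries (adjusted p = 0.0778). The H3K27ac region with the smallest p in GFP-positive nuclei, on chromosome 7 (125354502 to 125355762), carried 3.7 and 4.8 in Lep24 against 14.7 and 17.8 in Fast. In GFP-negative nuclei the regions were on chromosome 18 for H3K27ac (60721637 to 60722419), listed at 0 in both Lep24 libraries and at 6.6 and 5.0 in Fast, and on chromosome 12 for ATAC (101568554 to 101568874), at 0 and 2.2 against 10.1 and 5.7.

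At an unadjusted p under 0.05, Lep24 against Fast gave 3011 H3K27ac regions in GFP-positive and 6884 in GFP-negative nuclei, and 2933 and 653 ATAC regions. The smallest adjusted p was 0.942 and 0.714 for H3K27ac, and 0.0778 and 1 for ATAC. The test between sorts called 0 regions, with 2464 H3K27ac and 1301 ATAC regions at an unadjusted p under 0.05. As for Lep2, the fit of the 10 H3K27ac libraries took its spread from the Fast groups alone. Among the 10 H3K27ac libraries, with Lep24 left at 1 library per sort, 4 regions were called in GFP-positive nuclei, all lower, and 854 in GFP-negative nuclei (110 higher, 744 lower). Leaving out an H3K27ac library gave 1 call without Fast GFP-positive replicate 1, 18 without Fast GFP-negative replicate 1 and 1 without Lep24 GFP-negative replicate 1. For ATAC, leaving out Fast GFP-positive replicate 1 gave 1559 calls and 492 between sorts. Leaving out Fast GFP-positive replicate 2 gave 18 and 1, Lep24 GFP-positive replicate 1 14, Lep24 GFP-positive replicate 2 1 and Fast GFP-negative replicate 1 3.

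**Figure D4:**
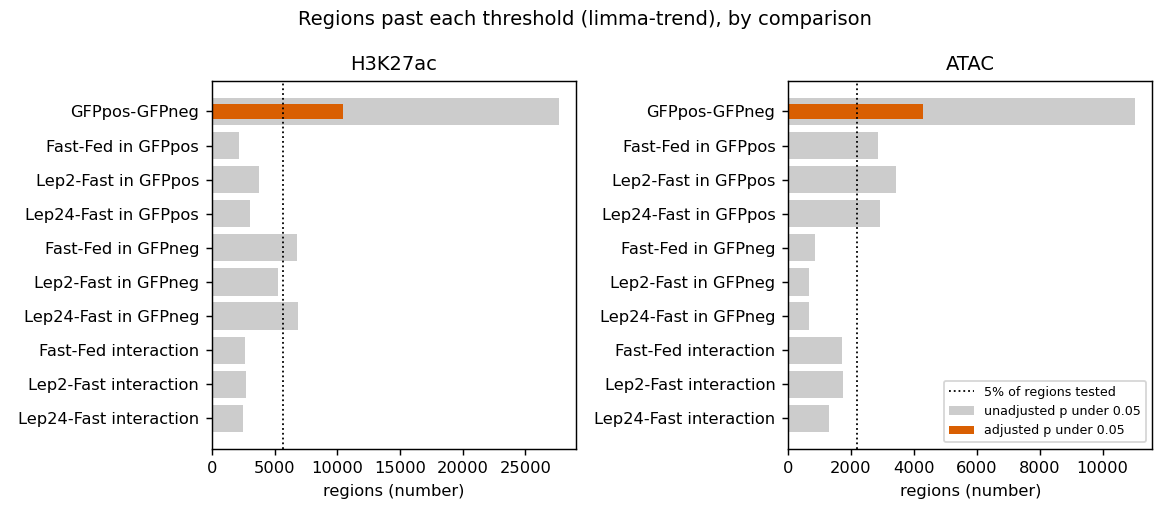
Number of regions past each threshold (limma) in the sort comparison, in each treatment comparison within a sort and in each test of a difference between sorts, for H3K27ac and ATAC. Grey bars give regions at an unadjusted p under 0.05, orange bars those at an adjusted p under 0.05, and the dotted line marks 5% of the regions tested; orange bars appear for the sort comparison, at 10491 and 4287, and the treatment comparisons have 0.

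The authors' deposited table lists 0 regions at an FDR under 0.05 for leptin against saline in either assay. That holds for its comparisons within each sort and for its leptin terms, whose fold changes in the authors' deposited table followed the change against Fast in GFP-negative nuclei (rho across regions 0.771 to 0.902) more closely than that over both sorts (0.603 to 0.69). For H3K27ac they followed most closely the change against the mean of Fed and Fast in GFP-negative nuclei (0.859 and 0.863). It lists 1 region whose response to repeated leptin differed between sorts, in H3K27ac on chromosome 4 (145591930 to 145615018), with an authors' log2 fold change of −17.95 and an FDR of 0.00475 in the authors' deposited table. The limma fit gave −3.27 with an SE of 3.30 there (adjusted p = 1).

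To see whether repeated leptin moved the chromatin of fasted GFP-positive nuclei towards the fed state, the Lep24 minus Fast change was set against the Fed minus Fast change across all regions tested. With all libraries the covariance of the changes was 0.131 (r = 0.72) in H3K27ac and 0.164 (r = 0.65) in ATAC. For unchanged groups measured against the same 2 Fast libraries, 0.099 (r = 0.50) and 0.091 (r = 0.50) were simulated. The simulation took a spread shared by all groups, which need not be that of the Fast GFP-positive libraries. With each Fast library used for only 1 of the changes, nothing was left in ATAC: the covariance was −0.011 and −0.033 for the 2 ways of sharing them out. In H3K27ac it was 0.079 and 0.083, but only 0.009 and 0.010 among the 10 libraries that remain without the 6 that stood apart. No move of fasted GFP-positive chromatin towards the fed state by repeated leptin was thus seen apart from the shared Fast libraries and the set of 6.

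With both Fast libraries shared, the H3K27ac covariance among the 10 libraries was 0.059 (r = 0.36), against 0.046 (r = 0.33) simulated with the spread of those 10 libraries, and with replicate 2 of Fed and Lep24 in ATAC it was 0.161 (r = 0.41), against 0.088 (r = 0.33) with the spread of the 14 libraries kept. Without Fed GFP-positive replicate 1 the H3K27ac covariance was 0.076 and without Lep24 GFP-positive replicate 1 0.075, both among the 6 libraries. In ATAC the covariance was 0.093 after quantile normalization (0.084 simulated). It was 0.067 with a pseudocount of 5 (0.046 simulated) and 0.402 with 0.1 (0.148 simulated). Without Fast GFP-positive replicate 1 the ATAC covariance was 0.538, but without replicate 2 it was 0.164 (0.181 simulated for each). Leaving out Fast GFP-positive replicate 1 and 2 in turn gave 0.183 and 0.179 in H3K27ac (0.197 simulated for each). All these simulated values rest on a spread shared by the groups. The Fast GFP-positive replicates, however, correlated at 0.966 in H3K27ac, the highest of any group, and at 0.798 in ATAC, the lowest. The simulated values may thus be too high for H3K27ac and too low for ATAC. Whether a covariance lay above or below them therefore decides nothing here. No p-value is given, since regions are not independent.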

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

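The splits of the libraries were planned before the result was seen, whereas the tests on slopes, X-linked regions and Y-linked regions were chosen after the result was seen.

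The difference between GFP-positive and GFP-negative nuclei in H3K27ac was smaller in the pairs of libraries made of replicate 1 of Fed, Lep2 and Lep24. The highest slope of the 3 pairs on the ATAC contrast was 0.22, below 0.51, the lowest of the other 5 pairs, which restates the pattern and cannot tell whether lower ChIP enrichment was the cause. A weakening by leptin as large as the gap between the sets of pairs did not appear in the 2 leptin pairs outside the 6 libraries. Their mean slope was 0.57, against 0.61 in the 2 Fast pairs. A smaller weakening was not excluded, as both leptin pairs (0.58 and 0.56) lay below both Fast pairs (0.63 and 0.59). Fed replicate 2, without leptin, lay at 0.51. Lower enrichment and another difference in handling between the 2 sets of libraries could not be told apart.

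The same 6 libraries had lower H3K27ac at X-linked regions. Low enrichment alone lowers signal-dense regions, yet X-linked regions lay below autosomal regions of matching density in all 5 density classes, nearest at −0.33. Density was the mean signal per length over all libraries, whatever share of it came from ChIP enrichment. The matching therefore cannot exclude low enrichment alone. A larger share of female nuclei would not be expected to lower X-linked regions, which lay −0.51 from autosomal ones at the median of the classes. Y-linked regions could not settle this: the 5 tested from 233980 to 623464 lay −1.49 from matching autosomal regions and the other 24 lay 3.61 above them (medians, of 29 tested). A change in how chromosomes were handled upstream may equally apply.

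The sort difference was set against 99 other splits of the libraries into 8 and 8, with treatment as a term. For ATAC 1 of 100 splits, the real split, called as many regions (5048, highest other split 68). For H3K27ac 2 of 100 splits did so, the real split with 14152 and another with 17948, which put replicate 2 of Fed, Lep2 and Lep24 in both sorts together with replicate 1 of Fed and Lep2 GFP-positive, and so divided the 6 libraries 4 to 2. The 2 splits that followed the library set, with all 6 on the same side and any call, called 10812 and 11514 regions, fewer than the sort. By the limit set beforehand, fewer than 5 of 100 splits, chance was argued against in both assays. The other splits mixed the sorts and the set of 6, so those differences added to the spread. Only 3 of the 99 other splits for H3K27ac and 6 for ATAC called any region. For H3K27ac 1 of the 99 passed the sort, so library structure apart from the sort could give as many calls.

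Single libraries stood apart in 9 of 88 groups of 8 values, where about 4.4 would by chance. In H3K27ac, the region on chromosome 13 (93163907 to 93165677) reached 68.6 in Lep24 GFP-positive replicate 2 (next 51.0). The region on chromosome 1 (139662105 to 139666042) reached 44.9 in Lep2 GFP-positive replicate 1 (next 24.6). Fed GFP-positive replicate 1 had 62 distinct values below 20 (next 23). In ATAC, the region on chromosome 2 (172159996 to 172160547) reached 36.3 in Lep24 GFP-positive replicate 1 (next 22.2). On chromosome 14, the region 114334257 to 114334861 reached 18.4 in Lep24 GFP-positive replicate 2 (next 9.3), and that on chromosome 1 (184405083 to 184405908) 15.1 in Lep2 GFP-positive replicate 2 (next 9.1). On chromosome 10, the region 21372181 to 21373552 reached 69.3 in Lep2 GFP-negative replicate 2 (next 49.5). Lep2 GFP-negative replicate 1 had 39 distinct ATAC values below 20 (next 26), and Fed GFP-negative replicate 1 the lowest ATAC difference between signal-dense and sparse regions, 2.379 (next 2.554).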

How the results depend on the processing

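Library weights, the set of 6 H3K27ac libraries as a term, the 10 other H3K27ac libraries alone ATAC without 2 outlying GFP-positive libraries (Fast replicate 2 and Lep2 replicate 2) and Fast libraries not shared between changes were chosen after the result was seen, and the other alternatives were planned. The H3K27ac sort count of 10491 (3707 higher, 6784 lower) became 3114 at an adjusted p of 0.01, 30225 with the library set as a term (14964 higher, 15261 lower), 36924 with the 10 libraries (18871 higher, 18053 lower), 18444 with replicate number as a block, 28570 with pairs of libraries as a block, and 5188 to 13898 with each library left out. The ATAC count of 4287 became 1360 at an adjusted p of 0.01, 6481 with pairs as a block and 2457 to 5686 with each library left out. Within treatments the replicate block gave 3818 H3K27ac regions between sorts in Fast (117 without it) and 275, 406, 96 and 7 ATAC regions in Fast, Lep2, Fed and Lep24 (24, 87, 7 and 0 without it). The labels do not say whether the numbers pair the sorts, and the main fits did not take them as pairs, so block fits are given here only. Deviations of same-treatment libraries correlated at 0.01 to 0.495 in H3K27ac and 0.037 to 0.141 in ATAC. Those of other pairs correlated at −0.164 to 0.55 and 0.024 to 0.176. The naming rule, the slopes per pair and the sign-flip test of X-linked regions did use the numbers as pairs. The share of ATAC sort calls matched in H3K27ac, 23.3%, was 44.4% with the library set as a term and 51.8% with the 10 libraries. With pairs as a block it was 43.2%, and these H3K27ac lists were all longer than the main one. With each library left out the share was 14.9 to 28.2%. All 32 named regions kept sign and call throughout. Treatment and sort-by-treatment counts, 0 throughout in limma (unadjusted counts stand in the results), stayed 0 in 122 of 138 H3K27ac values and 97 of 129 ATAC values. With the 10 H3K27ac libraries the calls were 99 for Fast against Fed in GFP-negative and 1 in GFP-positive nuclei, 1 for Lep2 against Fast in GFP-positive nuclei, and 4 in GFP-positive and 854 in GFP-negative nuclei for Lep24 against Fast. A pseudocount of 0.1 gave 1 H3K27ac call for Fast against Fed in GFP-negative nuclei. In ATAC GFP-positive nuclei it gave 3 for Fast against Fed, 5 for Lep2 against Fast and 4 for Lep24 against Fast, with 1 between sorts for Lep24, and a pseudocount of 5 gave 2 for Lep2. Without the 2 outlying ATAC libraries the GFP-positive calls were 16 for Fast against Fed, 1 for Lep2 and 23 for Lep24, with 1 between sorts for Fast against Fed and 1 for Lep24. The replicate block gave 3 ATAC calls for Lep2 and 8 for Lep24 in GFP-positive nuclei. Leaving out each library moved the ATAC GFP-positive counts over 0 to 1382 (Fast against Fed), 0 to 1492 (Lep2) and 1 to 1559 (Lep24), the sort-by-treatment counts over 0 to 594, 0 to 503 and 0 to 492, and the GFP-negative counts over 0 to 7, 0 to 7 and 0 to 3. The upper ends in GFP-positive nuclei came without Fast replicate 1, which left as control Fast replicate 2, the ATAC library with the fewest distinct values below 20 (8). In H3K27ac the ranges were 0 to 25, 0 to 5 and 0 to 18 in GFP-negative nuclei, 0 to 1 for each in GFP-positive nuclei and 0 to 1 between sorts for Fast against Fed. A group left with 1 library was assumed to spread like the other groups. Among the 10 H3K27ac libraries only the Fast groups kept 2, so in the fit of the 8 groups Fast alone gave the spread. The ATAC covariance of the Lep24 and Fed changes, 0.164, was 0.402 with a pseudocount of 0.1, 0.067 with 5, 0.093 after quantile normalization, 0.154 to 0.538 with each library left out, and −0.011 and −0.033 with Fast libraries not shared, and that of H3K27ac, 0.131, ranged over 0.059 to 0.188. Input filtering, total scaling, count models and gene lists did not apply or were not run.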

Other observations

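The tests of X-linked regions, Y-linked regions and runs of neighbouring regions were all chosen after the result was seen.

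Some of the lower H3K27ac in GFP-positive nuclei lay in long stretches of chromatin. On chromosome 10, a stretch of 176.5 kb (40071528 to 40248062) held 17 tested regions, 15 of them called lower by a mean log2 of −1.22, and 2 of its 4 ATAC regions were called less open. Stretches of 112.2 kb on chromosome 8 (87222444 to 87334682), with 11 of 13 regions called lower, and of 68.9 kb on chromosome 17 (66046140 to 66114990), with 12 of 14, had mean log2 changes of −1.26 and −1.07. On chromosome 4, 2 stretches (97416726 to 97519385 and 97530738 to 97621647) each had 10 of 12 regions lower. Of the 6784 lower calls, 68 lay in 6 runs of at least 10 called regions with gaps of at most 10 kb, and none of 100 shuffles of the calls gave such a run (0), although neighbouring regions are pieces of the same domains and not independent.

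Among the stretches of higher H3K27ac, none had 10 called regions (0 runs), but with 3707 higher calls against 6784 lower ones the directions were not compared. A 42.8 kb stretch on chromosome 4 (101353935 to 101396742) had all 6 regions called higher, by a mean log2 of 1.30, and all 3 of its ATAC regions called more open. A stretch of 43.9 kb on chromosome 6 (5322199 to 5366051) also had 6 of 6 regions called higher, with 2 of 7 ATAC regions more open, and a stretch of 27.2 kb on chromosome 13 (58542035 to 58569187) had 7 of 7.

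Relative to density-matched autosomal regions, X-linked H3K27ac was higher in GFP-positive than GFP-negative nuclei in all 8 library pairs with the same treatment and number. The mean log2 excess was 0.16 (0.05 to 0.28, exact sign-flip p = 0.00781, the smallest this test can give). ATAC did not show it (−0.05, exact sign-flip p = 0.109). GFP-positive ATAC libraries were mostly the less enriched of their pair, with differences from −0.339 in Lep2 replicate 2 to 0.131 in Fed replicate 1. The assays therefore cannot be set against each other here. The labels do not say whether the numbers pair the sorts. A difference not matched for density was therefore also tested (mean log2 0.18 in H3K27ac and −0.05 in ATAC). With sort labels exchanged within treatments its exact p was 0.204 for H3K27ac and 0.134 for ATAC. Exchanged within treatments and within the set of 6 or of 10 libraries, the exact p was 0.00521 for H3K27ac (2 of 384 arrangements, the fewest possible). Outside Fast, that exchange was between libraries with the same treatment and number, so it largely repeats the sign-flip test. The set of 6 was defined after the values were seen. Higher ChIP enrichment in GFP-positive libraries might raise the X-linked excess. In the 2 pairs where the GFP-positive library was not the more enriched (by −0.052 and −0.103), the mean was still 0.12. Over the 5 pairs outside the set of 6, however, the excess rose with the enrichment difference, from 0.114 to 0.277. In the 3 pairs within that set, with enrichment differences of 0.289 to 0.509, it was 0.047 to 0.162. The test takes the numbers as pairs, and a part played by enrichment was not excluded. A larger share of female nuclei among GFP-positive nuclei could raise X-linked and lower Y-linked signal: over 5 pairs the sum over 6 Y-linked regions from 233980 to 623464, picked after the values were seen, did not fall (mean log2 0.06, −0.14 to 0.26), but all 29 tested had a mean of 0.00 with an SD of 0.63, so this stays open. A higher X-linked H3K27ac of LepRb cells themselves remains possible and was not tested.

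Of the Y-linked regions, a single H3K27ac region (2026175 to 2032404) carried 585.2 in Fed GFP-negative replicate 1 and 82.8 in Fed GFP-positive replicate 1, and at most 2.3 in the other 14 libraries.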
